A study of Mus musculus with 2 samples.

How the data were processed

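The data were RNA-seq libraries labelled as mouse retina, 1 from wild-type (WT) mice and 1 from mice lacking the microRNA miR-29a (KO). Per the labels' protocols, the mice were C57BL/6 and 8 weeks old, the retinas of 3 mice were pooled for each library, ribosomal RNA was removed from total RNA with a Ribo-Zero kit, and libraries were made with a NEBNext Ultra RNA kit, which does not mark strand, and sequenced on an Illumina HiSeq instrument. The deposited tables give a read count and an FPKM value per gene for each library, per the file headers. The aligner was HISAT2 and the genome build mm10 (GRCm38), per the submitters' processing notes. The read counter, the annotation release, the strand setting and the way FPKM was scaled are not given in the sources used here. The authors' counts were whole numbers and were used as deposited. The authors' FPKM values entered only as an alternative.

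Each table held 52636 genes, of which 52403 had an identifier in GENCODE M21 (GRCm38), the source of positions, biotypes, transcript lengths and 3' UTRs. For 4 genes the ratio of count to FPKM differed between the tables by more than 1%, and they were left out (the entries named Crybg3 and Gm15853). A pair of genes carried a different symbol in each table, and 96 symbols were shared by 2 or more identifiers. The total of counts was 26805902 in the library labelled WT and 24876925 in the library labelled KO. A count of 0 allows up to 3 counts, which is 0.112 CPM (counts scaled to a common library total) in the library labelled WT and 0.121 CPM in the library labelled KO.

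Counts were divided by their total to give CPM, and the log2 ratio of KO over WT was taken after adding 0.5 to each CPM. A gene entered with 50 or more counts in the higher library. Folds were ratios of CPM with no addition, given with 95% exact (Clopper-Pearson) counting intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. With 1 library per group there are no replicates, no replicate check and no p-value across genes; all differences compare these 2 libraries, not the genotypes. Genes were counted as higher or lower at an absolute log2 ratio of 1 or more. Where 1 library had 0 counts, the fold was given as the limit of its counting interval nearer to 1.

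Gene lists were fixed before the data were examined, as were the rule for named genes and the alternatives, apart from the additions named here as made after the data were seen. The 43 lists covered miR-29 targets named in earlier work (extracellular matrix, DNA methylation, cell death and other targets), cell type markers (rod and cone photoreceptor, bipolar, horizontal, amacrine and retinal ganglion cell, Mueller glia, astrocyte, microglia, endothelial cell, pericyte and smooth muscle), markers of tissue a dissection could carry (retinal pigment epithelium, lens, corneal and surface epithelium, skeletal muscle, fibroblast, oligodendrocyte and optic nerve, red blood cell), and processes (collagens, glial stress response, complement, interferon response, immediate early, heat shock, integrated stress and unfolded protein response, antioxidant, circadian clock, mitochondrially encoded, nuclear oxidative phosphorylation, cytosolic ribosomal proteins, replication-dependent histones, glycolysis, cholesterol synthesis, synaptic ribbon and vesicle, visual cycle and retinoid, small RNA processing). Y-linked genes, X inactivation genes and genes that differ between C57BL/6 substrains were checks. The median log2 ratio of each list with 3 or more members past the count minimum was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was called apart from the rest below the 2.5 or above the 97.5 percentile. Members of a list are co-regulated, so the percentile describes these libraries and is not a test of genotype. A further 4 lists were added after the data were seen, with members whose values had not been looked at: macrophage, interferon-stimulated, hypoxia-induced and X-inactivation escape genes.

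A miR-29 site was the heptamer TGGTGCT, the reverse complement of bases 2 to 8 of miR-29a, in the longest annotated 3' UTR of a protein-coding gene. Genes with no annotated 3' UTR were not searched. The difference of medians between genes with and without the heptamer was ranked among 140 heptamers made by permuting its letters, itself included. Named genes were the 12 with the largest increase and the 12 with the largest decrease among genes past the minimum whose symbol is not a model, clone or pseudogene name, the 3 members of each list with the largest absolute log2 ratio and up to 2 with the highest expression, the members of the check lists, and the genes near Mir29a past the minimum. A few genes that this rule takes in are not reported here. Any other gene named was chosen after its values were seen.

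Alternatives to these choices were edgeR's TMM factors, median-of-ratios factors, a total without mitochondrial, rRNA and the 20 most counted genes, pseudocounts of 0.1 and 2 CPM, a minimum of 200 counts or none, protein-coding genes only, thresholds of 1.5-fold and 4-fold, matching on length, 8-mer or 2 or more sites, target lists without the matrix list or limited to genes with a heptamer, and a window of 2 Mb around Mir29a. Added after the data were seen were a correction that subtracted the median of genes in the same of 10 bins of transcript GC content and of 10 bins of transcript length, the authors' FPKM (with 0.5 added to each value), matching of the target lists on 3' UTR length, the heptamer rank under each setting, and the GC and length correction of the X-inactivation escape genes.

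The procedure was tested on simulated counts drawn from the means and totals of these 2 libraries. Of 12221 simulated genes past the minimum, the counting interval held the true ratio for 95.3%. Of the genes changed by 2-fold, 97.9% of 95 were recovered with the right sign and an absolute log2 ratio of 0.585 or more, and of those changed by 4-fold, 100% of 104; 0 unchanged genes passed the size threshold. Of 200 unshifted lists of 15 genes, 6% fell outside the 2.5 to 97.5 percentiles, and 100% of 50 lists shifted up by 0.5 were placed above. These simulations hold counting error and no biological spread. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.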

Results

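Per the labels, gene expression was measured by RNA-seq in retina of 8-week-old C57BL/6 mice. The labels give 1 library from wild-type mice and 1 from mice lacking miR-29a, each made from pooled retinas of 3 mice. The library labelled WT held 26805902 counts over 19346 genes with a count, and the library labelled KO 24876925 counts over 19545 genes. Protein-coding genes took 97.8% and 98.2% of the counts, and rRNA genes 0.0221% and 0.0246%. The 20 most counted genes of each library took 11.3% and 11.5%, led by the elongation factor Eef2 (1.17%) in the library labelled WT and the secreted phosphoprotein Spp1 (1.75%) in the library labelled KO. Because the marker content described next went against the tissue named in the labels, the libraries are called by their labels throughout.

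Most marker transcripts of retinal neurons were close to 0 in both libraries, with a few abundant exceptions. The cone pigment gene Opn1sw had 4 counts in the library labelled WT (0.149 CPM, counting interval 0.0407 to 0.382) and 4 in the library labelled KO (0.161 CPM, 0.0438 to 0.412). The rod genes Gnat1 (1 and 0 counts) and Sag (0 and 3), and the cone pigment gene Opn1mw (0 and 1) were also low. The bipolar cell gene Grm6, the ganglion cell gene Pou4f2, the amacrine cell gene Gad1 and the horizontal cell gene Lhx1 had 0 counts in both, which allows up to 0.112 CPM and 0.121 CPM. Of 75 photoreceptor, bipolar, horizontal, amacrine and ganglion cell markers, 57 lay under 1 CPM in the library labelled WT and 55 in the library labelled KO, and their medians were 0.0373 and 0.0402 CPM. In each library 16 markers had 50 or more counts. The 15 with that many in both included Stmn2 (463 and 500 CPM) and Thy1 (115 and 218 CPM) of the ganglion cell list. The widely expressed rod list member Gnb1 (315 and 381 CPM) was another. Stmn2 and Thy1 alone do not show ganglion cell RNA, since Pou4f2 had 0 counts in both libraries and Pou4f1 1 in each. The ganglion cell list summed to 641 and 781 CPM, mostly from Stmn2 and Thy1, with a member median of 0.970 and 1.57 CPM. Mueller glia markers were mixed, with Rlbp1 at 24 and 11 counts and Aqp4 at 0 in both, but Apoe at 452 and 440 CPM, Clu at 325 and 229 CPM and Glul at 139 and 170 CPM. The Mueller glia list summed to 1348 and 1199 CPM, with a member median of 3.36 and 1.09 CPM.

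The fibroblast markers, fixed as a sign of carried-over connective tissue, were among the most abundant transcripts. Their median was 475 CPM in the library labelled WT and 618 CPM in the library labelled KO, at the top 1.51% and 1.11% of detected genes. Igfbp4, which encodes an insulin-like growth factor binding protein, reached 5469 and 6266 CPM, the matrix protein gene Mgp 2558 and 2734 CPM, and the proteoglycan gene Dcn 995 and 1895 CPM. Col1a2, a type I collagen gene outside this list, reached 2757 and 2648 CPM. Genes in none of the lists were abundant too, among them Fn1 (10946 and 10549 CPM) and Lgals1 (9405 and 6354 CPM). Vim reached 3677 and 4381 CPM, and the noncoding RNA gene H19 3275 and 1955 CPM. Markers of lens (5.22 and 4.42 CPM summed over 21 genes) and red blood cells (0.0373 and 0.161 CPM over 6 genes) were scarce. The corneal and surface epithelium list summed to 477 and 772 CPM, nearly all from the aldehyde dehydrogenase gene Aldh3a1 (12759 and 19212 counts), and the oligodendrocyte and optic nerve list to 66.1 and 45.8 CPM, mostly from Cnp (1738 and 1076 counts). The astrocyte gene Gfap had 5 counts and 1 count, and the pigment epithelium gene Rpe65 had 0 in both.

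**Figure D1:**
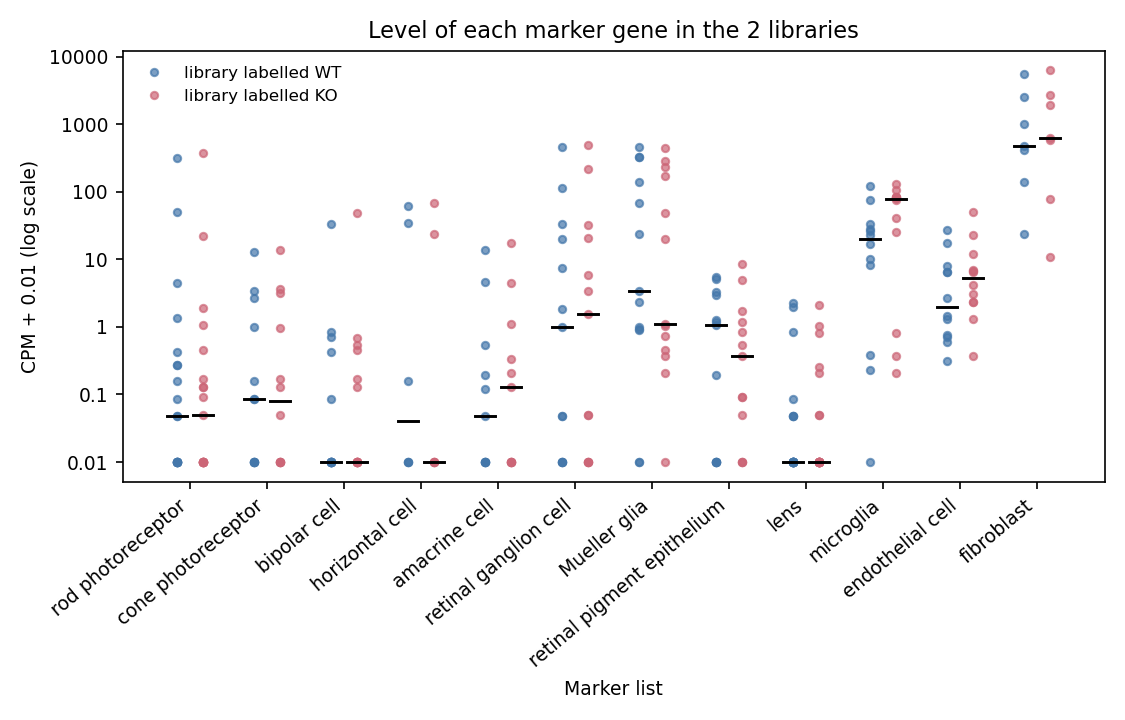
Level of each marker gene in CPM (log axis, 0.01 added) for 12 marker lists, with 1 point per gene and library and a black bar at the list median. Medians of the retinal neuron lists lie near or under 1 CPM in both libraries, while the fibroblast medians are 475 and 618 CPM.

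Genes on the sex chromosomes differed between the libraries. Xist, the RNA that coats the inactive X chromosome, had 4288 counts in the library labelled WT and 0 in the library labelled KO. It was at least 1078-fold lower in the library labelled KO. All 4 Y-linked genes were higher in the library labelled KO: Kdm5d with 30 and 310 counts (11.1-fold, 7.64 to 16.8), Ddx3y with 67 and 376 (6.05-fold, 4.65 to 7.96), Eif2s3y with 50 and 280 (6.03-fold, 4.45 to 8.33) and Uty with 17 and 126. Their median log2 ratio was 2.35, at the 100 percentile of matched random lists. Tsix had 0 counts in both libraries. Of the genes that differ between C57BL/6 substrains, Nnt had 2 and 8 counts, Crb1 0 and 0, and Cyfip2 77 and 105.

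The first question of the comparison was the targeted locus on chromosome 6. Mir29a (ENSMUSG00000065610, positions 31062660 to 31062747, GRCm38) and the neighbouring Mir29b-1 (31063023 to 31063093) had 0 counts in both libraries. A precursor of this length is seldom counted by such a library, so these values check neither label. Of 32 genes within 500 kb, 8 passed the count minimum, with a median log2 ratio of 0.64, and 2 passed the 2-fold threshold. Lncpint, a long noncoding RNA gene, begins 19818 bp away (31082565 to 31220488). It had 0 counts in the library labelled WT and 64 in the library labelled KO, at least 18.2-fold higher. Podxl, which encodes the sialomucin podocalyxin, had 36 and 118 counts (3.53-fold higher, 2.41 to 5.28). The log2 ratios of the others were 0.78 for the processed pseudogene Gm13835, 0.32 for 2210408F21Rik, 0.49 for Copg2, -0.78 for Mest, 0.82 for Mkln1 and 0.09 for Cep41. Lncpint overlaps other annotated transcripts and strand was not marked, so its reads cannot be assigned with certainty. In the window of 2 Mb, 28 of 99 genes passed the minimum, with a median log2 ratio of 0.27, and the same 2 passed the threshold. A gene with no position in the annotation, such as Gm13834 (0 and 224 counts), could not enter either window.

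Across all genes, 12382 passed the count minimum, of which 554 were higher in the library labelled KO by 2-fold or more, 349 were lower and 11479 were neither. The whole counting interval lay beyond 2-fold for 372 of the higher and 225 of the lower genes. The median log2 ratio was 0.06, with 25th and 75th percentiles of -0.25 and 0.37. Across genes, which are not independent replicates, log2 CPM correlated between the libraries with Pearson's r of 0.958, and the log2 ratio with transcript GC content with Spearman's rho of -0.441 and with transcript length with rho of 0.149.

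Of the 12 genes with the largest increase, the cell adhesion gene Nrcam was 16.0-fold higher (35 and 520 counts, 11.4 to 23.2) and the synaptic vesicle fusion gene Snap25 was 14.3-fold higher (27 and 359 counts, 9.68 to 22.0). Npy, which encodes neuropeptide Y, was 10.6-fold higher (7.68 to 15.1) and the incretin receptor gene Glp1r 26.0-fold higher on 6 and 145 counts (11.7 to 72.1). The chemokine receptor gene Ccr1 was 9.46-fold higher (7.40 to 12.2), and the protease inhibitor gene Serpinb2 had 572 and 4581 counts (8.63-fold higher, 7.91 to 9.43). Psca had 0 and 129 counts, at least 37.1-fold higher. The glycosyltransferase gene Gcnt1 (13.2-fold), the calcium pump gene Atp2a3 (8.94-fold) and Atp10d (22 and 266 counts) made up the list with Kdm5d and Rbpsuh-rs3 (14.0-fold). Rbpsuh-rs3 is annotated as a processed pseudogene, so its reads are uncertain.

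Of the 12 genes with the largest decrease, Xist came first. Ndufa4l2, a gene known to be induced by low oxygen, was 35.4-fold lower in the library labelled KO (840 and 22 counts, 23.2 to 56.9). Slc16a3, the lactate exporter, was 8.71-fold lower (7.95 to 9.56). Comp, which encodes the cartilage oligomeric matrix protein, was 9.17-fold lower (14373 and 1455 counts, 8.69 to 9.68), and the ubiquitin-like interferon-induced gene Isg15 8.99-fold lower (8.12 to 9.98). Prok2, which encodes prokineticin 2, was 19.5-fold lower (967 and 46 counts) and Pianp 14.0-fold lower (2511 and 166 counts). The complement protease genes C1s2 (15.1-fold) and C1rb (12.4-fold), Apol9b (11.2-fold) and the MHC class I gene H2-Q6 (15.4-fold) were lower too. Hist1h2al had 534 and 0 counts, at least 134-fold lower. C1s2, C1rb, Apol9b, H2-Q6 and Hist1h2al have near-identical relatives with which reads could be shared, so their values are uncertain. All 24 genes lacked the miR-29 heptamer in the 3' UTR or had none searched. Pianp, C1s2 and C1rb lie close together on chromosome 6, between positions 124530345 and 125003096. The glycolysis genes Eno2 (log2 ratio -1.20) and Tpi1 (-0.93) lie in the same region, as does C1s1 (-0.19). Genes of this region were not tested as a group.

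The next question was whether genes with a miR-29 site, which a microRNA would repress, stood higher in the library labelled KO. Of 11585 protein-coding genes searched, 1860 had the heptamer TGGTGCT and a median log2 ratio of 0.14, and 9725 had none and a median of 0.05, a difference of 0.10. The site genes lay at the 100 percentile of random lists matched on expression, whose medians ran from 0.05 to 0.10, but at the 86.66 percentile when the lists were also matched on 3' UTR length, within the range of such lists. The median 3' UTR was 2473 bases with a site and 1048 without. Among 140 permuted heptamers TGGTGCT ranked 19, with control differences from -0.01 to 0.13. After the GC and length correction the median of the site genes was 0.04 and the difference of medians 0.04. By 2-fold, 3.98% of site genes were higher and 1.24% lower, against 4.53% and 2.71% of genes without a site. Median log2 ratios were 0.18 for 388 genes with an 8-mer and 0.17 for 304 genes with 2 or more sites.

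Published miR-29 targets were higher in the library labelled KO as a group, by a small margin. Of 52 listed targets 44 passed the minimum, and 6 were higher by 2-fold, 0 lower and the rest neither. The log2 ratio was above 0 for 33 and below 0 for 11, with a median of 0.29 at the 99.93 percentile, against -0.13 to 0.19 for random lists. The 6 were the DNA glycosylase gene Tdg (3.69-fold, 3.02 to 4.54), the growth factor gene Pdgfc (3.54-fold, 2.95 to 4.28), the type V collagen genes Col5a3 (2.80-fold, 2.55 to 3.07) and Col5a2 (2.11-fold, 2.03 to 2.19), and the cell cycle genes Ccnd2 (2.04-fold, 1.97 to 2.11) and Cdk6 (2.04-fold, 1.81 to 2.30). The DNA methyltransferase gene Dnmt3a had a log2 ratio of 0.60, Sparc 0.76, Col4a1 0.78, Mcl1 0.34 and Col1a2 -0.06, and the lowest value was -0.68 for the cell death gene Bbc3. By list, the other targets lay at the 99.97 percentile (median 0.46), the matrix targets at 93.98 (0.19), the DNA methylation targets at 95.69 (0.52) and the cell death targets at 43.2 (0.02). Markers of macrophages and endothelial cells, described next, were higher in the same library.

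**Figure D2:**
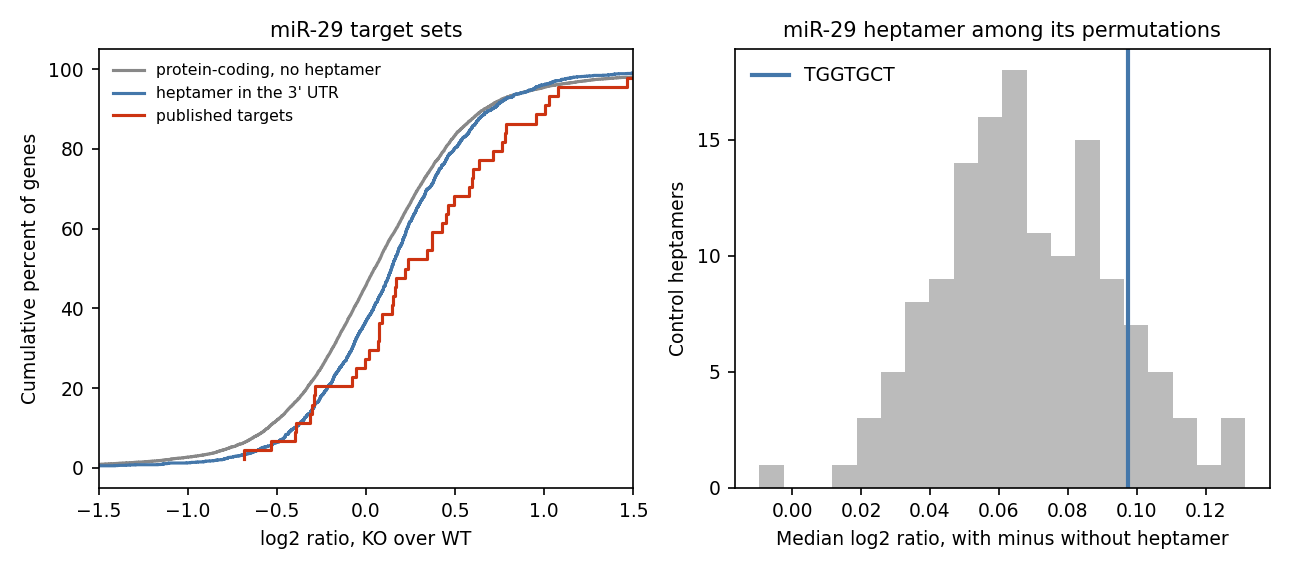
Left, cumulative percent of genes by log2 ratio of KO over WT for protein-coding genes without and with the miR-29 heptamer and for 44 published targets, drawn from -1.5 to 1.5. Right, number of control heptamers by the difference of median log2 ratios between genes with and without each, with TGGTGCT, at 0.10, as a line.

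Of the 43 lists, 34 had 3 or more members past the minimum. Of these, 7 stood apart as higher, the Y-linked check among them, and 5 as lower. If list members varied independently, 1.7 would be expected outside by chance. Members of a list are co-regulated, so more than 1.7 can fall outside by chance. The interferon response list stood lowest. Of its 19 measured members 13 were lower in the library labelled KO by 2-fold, 6 were neither and all 19 had a log2 ratio below 0, with a median of -1.53 (percentile 0). The transcription factor gene Irf7 was 6.57-fold lower (6.20 to 6.98), Usp18 5.78-fold lower (5.15 to 6.50) and the virus-tethering gene Bst2 4.07-fold lower (3.93 to 4.22), while Ifi27 had a log2 ratio of -0.45.

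Microglial markers, most of which macrophages share, were higher in the library labelled KO. Of 9 measured members 7 were higher by 2-fold, 2 neither and 0 lower, with a median log2 ratio of 1.79 (percentile 100). The protease gene Ctss was 4.83-fold higher (4.18 to 5.61), the signalling adaptor gene Tyrobp 4.44-fold (4.01 to 4.93) and C1qa 3.86-fold (3.58 to 4.16). Tmem119, a gene typical of microglia in neural tissue, had a log2 ratio of -0.54. C1qa, C1qb and C1qc are also members of the complement list, which lay at the 24.78 percentile with 3 members higher and 2 lower, among them the inhibitor gene Serping1 (2.20-fold lower, 2.11 to 2.29).

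Endothelial markers were higher for 5 of 10 measured members and lower for 0 (median log2 ratio 1.08, percentile 100). Cdh5, the endothelial cadherin, was 3.55-fold higher (2.99 to 4.22), Pecam1 2.95-fold (2.02 to 4.40) and the VEGF receptor gene Kdr 7.81-fold on 8 and 58 counts (3.71 to 18.9). With a minimum of 200 counts, which left 4 members, the list lay at the 77.41 percentile with a median of 0.31. Skeletal muscle genes were higher for 3 of 4 (median 1.06, percentile 99.02) at low counts, such as Tnni2 with 23 and 67 and Acta1 with 66 and 135.

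Genes of cholesterol synthesis were higher together by a small margin, with all 15 log2 ratios above 0, a median of 0.58 (percentile 99.99) and 1 member past 2-fold, the isomerase gene Idi1 (3.26-fold, 2.68 to 3.99). Msmo1 had a log2 ratio of 0.79. After the GC and length correction the median of this list was 0.37 (percentile 99.96). Cytosolic ribosomal protein genes were lower together, with 56 of 76 below 0 and a median of -0.30 (percentile 0). Of these 0 were 2-fold lower and 1 was higher, Rpl29 (2.65-fold, 2.53 to 2.78), a gene with many processed copies. Rps3 had a log2 ratio of -0.79 and Rplp0 -0.44, and the genes together took 11.6% of counts in the library labelled WT and 8.92% in the library labelled KO. Glycolysis genes had a median of -0.26 (percentile 1.555), with 15 of 19 below 0 and 2 past 2-fold, the phosphofructokinase gene Pfkl (2.62-fold lower, 2.52 to 2.72) and Eno2 (2.32-fold lower, 2321 and 930 counts). Tpi1 had a log2 ratio of -0.93 and Ldha, lactate dehydrogenase, -0.78.

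The remaining lists apart from the rest held few members. Replication-dependent histones lay at the 99.37 percentile (8 members, 3 higher and 1 lower, median 0.62), with Hist1h2bc 2.38-fold higher (2.18 to 2.61), but at 14.26 with a minimum of 200 counts, where the median turned to -0.24. After the GC and length correction their median was 0.38 (percentile 98.45). The rod list lay at the 0.17 percentile (3 members, 2 lower, median -1.05) on Rom1 with 1361 and 549 counts, Guca1a with 119 and 47, and the widely expressed Gnb1 with 8441 and 9476, and at 5.07 with no count minimum. The pigment epithelium list lay at 1.69 (4 members, 2 lower, median -0.76), with Ttr at 89 and 9 counts and Tyr at 80 and 21, and at 43.6 with no count minimum.

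**Figure D3:**
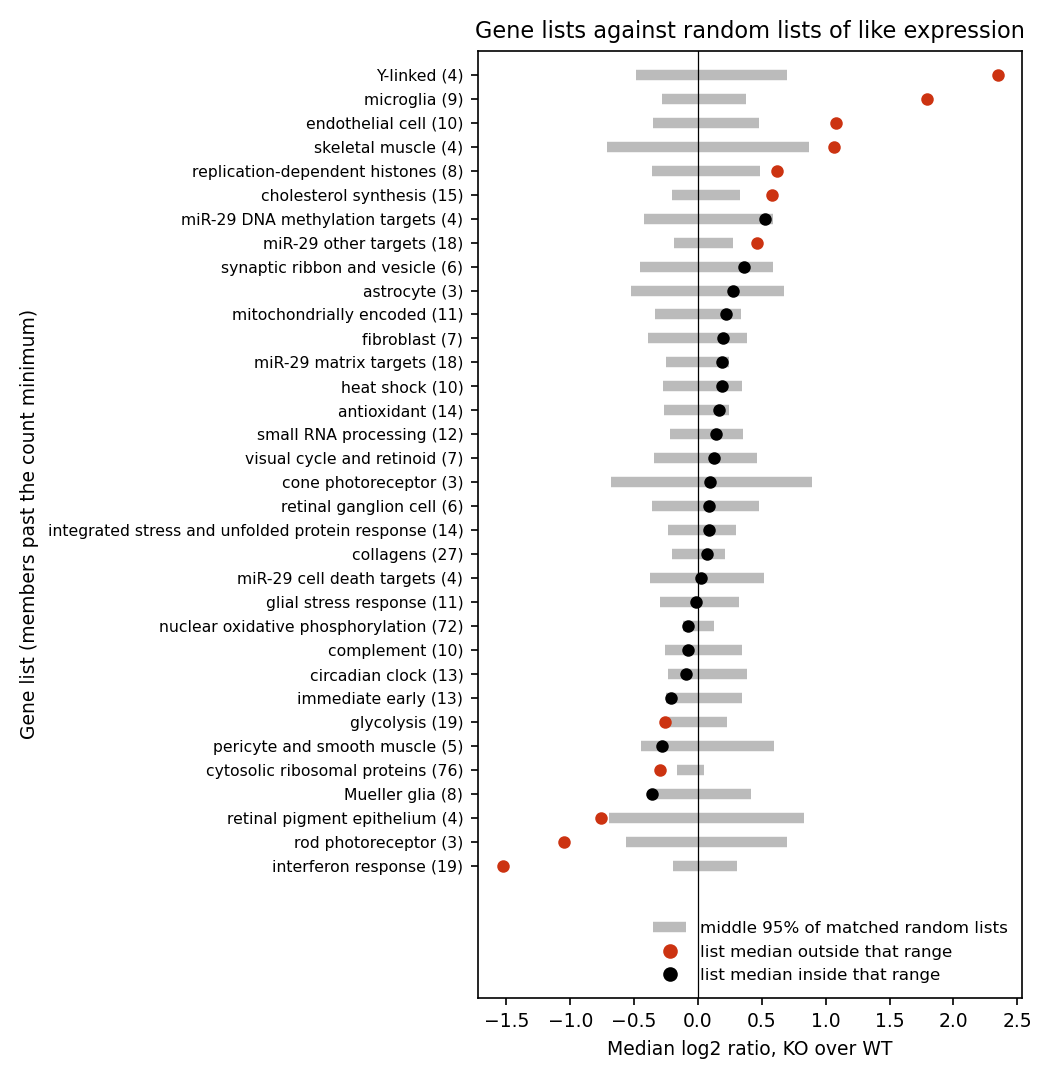
Median log2 ratio of KO over WT for the 34 lists with 3 or more members past the count minimum, each beside the middle 95% of medians of random lists matched on expression (grey bars). Red points mark the 12 lists outside their bar, from the interferon response at -1.53 to the Y-linked genes at 2.35.

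The other lists did not stand apart. Mueller glia markers lay at the 3.01 percentile with 2 of 8 lower (Crym 3.34-fold, 2.13 to 5.43, and Abca8a 3.20-fold, 1.87 to 5.74), immediate early genes at 4.395 with 1 of 13 higher (Egr3, 2.18-fold, 1.89 to 2.52), and nuclear oxidative phosphorylation at 9.02 with 2 of 72 lower (Cox6b2, log2 ratio -1.70, and Cox7a1, -1.60). Antioxidant genes lay at 92.27 with 2 of 14 higher (the cystine transporter gene Slc7a11, 2.44-fold, 2.27 to 2.62, and Gclc, 2.13-fold, 2.05 to 2.22), mitochondrially encoded genes at 90.495 with 3 of 11 higher (mt-Atp6, log2 ratio 1.49), and heat shock genes at 86.16 with 3 of 10 higher (Hsp90aa1 1.22, Hspd1 1.15 and Hspa8 1.03 on the log2 scale). The glial stress response lay at 49.96 with 2 of 11 higher (the lipocalin gene Lcn2, 5.12-fold, 4.83 to 5.43, and A2m, 4.37-fold, 2.54 to 7.93). Collagens lay at 74.59 with 3 of 27 higher and 2 lower (Col14a1 3.62-fold lower, 3.29 to 3.98), fibroblast markers at 87.39 with 1 of 7 lower (Dpt, 2.20-fold, 1.90 to 2.54), and synaptic genes at 87.81 with 1 of 6 higher (Snap25).

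In the following lists 0 members passed 2-fold. Percentiles were 65.01 for the integrated stress and unfolded protein response (Atf4, log2 ratio 0.52), 12.485 for the circadian clock (Nfil3, -0.87), 67.68 for small RNA processing (Ago2, 0.45), 59.68 for visual cycle and retinoid genes (Rdh11, 0.45), 58.42 for ganglion cell markers (Thy1, 0.92), 50.53 for cone markers (Gngt2, 0.09), 79.06 for astrocyte markers (Pdgfra, 0.38, also a fibroblast marker), and 8.58 for pericyte and smooth muscle markers (median -0.29, Notch3 -0.74 and Acta2 0.69). Lists with fewer than 3 measured members gave values only. These were the bipolar cell gene Prkca (log2 ratio 0.52), the horizontal cell genes Slc4a3 (-0.51) and Ndrg1 (0.13), the amacrine cell genes Slc6a9 (0.33) and Tfap2b (-0.06), the lens genes Crygn (-0.72) and Bfsp1 (-0.08), the surface epithelium gene Aldh3a1 (0.70) and the oligodendrocyte gene Cnp (-0.58); the other 3 such lists were red blood cell, X inactivation and substrain genes, given above.

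**Figure D4:**
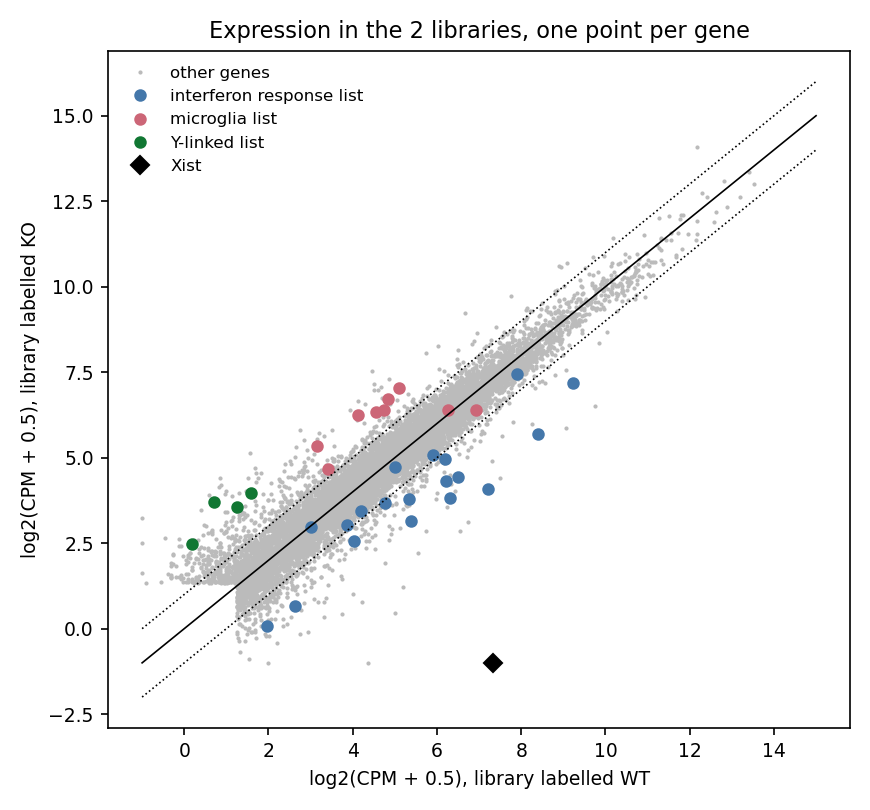
Each of the 12382 genes past the count minimum by log2(CPM + 0.5) in the library labelled WT (horizontal) and the library labelled KO (vertical), with the line of equality and dotted lines at 2-fold. Of the interferon response list 13 genes lie below the lower dotted line, 7 microglia genes and 4 Y-linked genes lie above the upper line, and Xist, with 0 counts in the library labelled KO, lies far below.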

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

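Among these alternatives, the GC and length correction, the authors' FPKM, the matching of published targets on 3' UTR length, the repeated heptamer ranks and the correction of the escape genes were chosen after the data were seen. No library could be left out and no paired analysis was possible because each group has a single library. All 24 genes of largest change kept their direction and stayed past 2-fold in each alternative that could be run for them. These were 10 for 18 genes and 9 for 6, since Psca and Glp1r have fewer than 200 counts and Rbpsuh-rs3, Atp10d, Xist and Hist1h2al are not annotated as protein-coding. Their sizes moved beyond the counting interval for 16 genes with a pseudocount of 2, 6 with the authors' FPKM and 4 after the GC and length correction. With 0.5 added to each FPKM the log2 ratio was 1.21 for Kdm5d, 1.79 for Nrcam, 1.63 for Atp10d, 2.02 for Snap25 and -4.31 for Xist, and with a pseudocount of 2 it was 1.85 for Psca, 1.82 for Glp1r and -3.45 for Hist1h2al (5.72 for Psca with 0.1). The FPKM ratios just listed shrank because of the added 0.5, while some others grew, such as Hist1h2al (-5.35 to -6.97) and Psca (3.51 to 3.73). With nothing added, the FPKM fold of each of these 24 genes counted in both libraries was 96.2% of its CPM fold. The 554 higher and 349 lower genes became 351 and 214 with a pseudocount of 2 CPM, 340 and 213 with a minimum of 200 counts, 1645 and 1100 at 1.5-fold, and 103 and 58 at 4-fold; with the authors' FPKM 322 were higher and 288 lower. A stricter minimum leaves fewer genes, and the other thresholds differ by construction. Published targets stayed apart as higher in every alternative (98.48 to 100), at 99.65 when matched on 3' UTR length. Genes with a miR-29 site fell to the 86.66 percentile when matched on 3' UTR length, and the heptamer's rank ran from 8 (GC and length correction) to 35 (no count minimum) of 140. At rank 8 the difference of medians fell from 0.10 to 0.04 and the site genes' median from 0.14 to 0.04. With median-of-ratios factors and FPKM the site genes' median was 0.08 and 0.07 (differences 0.10 and 0.08), and all genes' median shifted by -0.06. Of the 12 lists apart from the rest, 7 stayed so on the same side in all 11 alternatives, and skeletal muscle in the 10 that could be run, since fewer than 3 members reach 200 counts. The rod and pigment epithelium lists could not be run at 200 counts either. The rod list moved to 5.07 with no count minimum, the endothelial list to 77.41 with 200 counts, and the pigment epithelium list to 2.65 with a pseudocount of 2, 43.6 with no minimum and 8.7 with FPKM. Histones moved to 95.58 with no minimum and turned to 14.26 with 200 counts, which left 5 members. Where the list stayed apart, the median moved by more than 1.5 times for cholesterol synthesis (0.58 to 0.37) and histones (0.62 to 0.38) after the GC and length correction, endothelial (1.08 to 0.55) and Y-linked genes (2.35 to 1.47) with FPKM, and skeletal muscle (1.06 to 0.66 with a pseudocount of 2 and 0.67 with no minimum). The cause of the other moves was not tested. A further 8 lists stood apart in at least 1 alternative: collagens (99.685), matrix targets (99.91), antioxidant genes (97.95) and complement (0.1) after the GC and length correction, immediate early (1.965) and heat shock genes (99.1) with 200 counts, mitochondrially encoded genes (97.505) when matched on length, although their median turned from 0.22 to -0.16 (percentile 11.425) after the GC and length correction, and Mueller glia in several (0.65 to 2.35). That correction also changed the sign of the medians of the cell death target, immediate early and integrated stress lists, none of them apart from the rest before it. Depth limits genes near the floor of 0.112 and 0.121 CPM, such as Gnat1 and Sag, for which no ratio between the libraries can be read.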

Other observations

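The tests of photoreceptor loss, of a fibroblast-like population and of a male share were chosen after the result was seen, as were the macrophage, interferon-stimulated, hypoxia-induced and X-inactivation escape lists, although the values of their members had not been looked at, and the correction for GC content and length. The genes of this paragraph were chosen after their values were seen, and as no list or enrichment test stands behind them they describe no group. The chemokine genes Ccl2 (5.86-fold, 5.63 to 6.11) and Ccl7 (6.47-fold, 5.92 to 7.06), the epidermal growth factor receptor ligand genes Areg (6.86-fold, 5.78 to 8.18) and Ereg (5.49-fold, 5.08 to 5.94), Spp1 (3.81-fold, 3.79 to 3.83) and the metalloproteinase inhibitor gene Timp1 (2.36-fold, 2.33 to 2.40) were higher in the library labelled KO by 2-fold or more. Other genes for secreted proteins were lower there, among them the interferon-induced chemokine gene Cxcl10 (415 and 38 counts, 10.1-fold lower), Comp (14373 and 1455 counts), Prok2 (967 and 46) and Serping1 (8211 and 3467).

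The macrophage list, added after the data were seen, had 13 of 17 measured members higher by 2-fold and 0 lower, among them Adgre1, which encodes F4/80 (4.41-fold, 3.76 to 5.19), and Cd53 (5.08-fold, 4.08 to 6.38), while Cd14 had a log2 ratio of -0.16. Their median log2 ratio was 1.42. The abundant macrophage gene Lyz2, chosen after its value was seen, was 3.89-fold higher (3.78 to 4.01). A larger share of macrophages in the library labelled KO would give such a median. Microglial markers, most of which macrophages share, were already known to be higher, so this list is a weak test. It does not tell the share of cells from expression per cell. Hypoxia-induced genes lay at the 0.57 percentile with a median log2 ratio of -0.30, with 11 of 15 below 0 and 4 above 0. Ankrd37 (-1.54) and Pdk1 (-1.01) were the 2 past 2-fold. A lower hypoxia response would give such values beside the lower glycolysis genes, but both lists come from the same 2 libraries. Of the glycolysis genes, Eno2 and Tpi1 also lie in the chromosome 6 region named above. Neither hypothesis separates genotype from the other differences between these libraries.

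Most marker transcripts of retinal neurons were close to 0 in both libraries while connective tissue transcripts were abundant. Exceptions were Stmn2 (463 and 500 CPM), Gnb1 (315 and 381 CPM) and Thy1 (115 and 218 CPM). Which cells the transcripts of these exceptions came from cannot be read from such values. Loss of photoreceptors alone would have left the inner retina, but the median of the bipolar, horizontal, amacrine and ganglion cell markers was 0.0373 CPM in the library labelled WT. Loss of the markers in counting stays open: 63.2% of 144 neighbouring protein-coding genes reached 50 counts in either library, but a loss limited to the markers allows this, and their own low share was known beforehand, so the higher share set as the bound against this explanation was a wrong bound. The fibroblast markers had a median rank at the top 1.51% of detected genes in the lower-ranked library, but this is the observation itself and no separate test, so RNA of a fibroblast-like cell population, through a wrong sample or file, stays open as a candidate explanation.

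Xist and Y-linked transcripts differed between the libraries. Pools of different sex may explain this, but X-inactivation escape genes do not decide it: 5 measured genes had a median log2 ratio of 0.18, at the 57.965 percentile of matched lists of X-linked genes. That lies above the 50 percentile set beforehand as counting against this explanation, but within the -0.26 to 0.45 of random lists, and after the GC and length correction the median turned to -0.16, at the 30.38 percentile. Y-linked transcripts in the library labelled WT stood at 13.9% (11.8 to 16.4) of their level in the library labelled KO, from 8.98% to 16.6% by gene. A single male share giving all 4 ratios had a permutation p of 0.037, between the bounds set for and against it. That p covers counting error only. Sex-linked transcripts thus differed along with the labels, so sex cannot be told apart from genotype for any gene reported.

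Interferon genes were lower in the library labelled KO. A trend with GC content and length, which exists between these libraries, is argued against as the whole cause, since the median log2 ratio of the list was -1.80 after its removal and -1.53 before. A shift of interferon-stimulated genes as a whole is consistent with the added list, whose 21 measured members all had a log2 ratio below 0, with 9 past 2-fold (H2-K1, -1.49, and Ifi35, -1.53) and a median of -0.67 at the 0 percentile. Whether this came with genotype, with sex or with the state of the cells cannot be read from 1 library per group.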
